A study of Mus musculus with 12 samples.

How the data were processed

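RNA was measured in 12 libraries of mouse ileal enteroids, 3 per group, made with a directional poly(A) protocol per the labels. The deposited table gave, for each gene, the whole-number count of reads in each of the 12 libraries, which the authors had not normalised. It also held the authors' p-value, FDR and log2 fold change, plain and shrunken, of a DESeq comparison of untreated with IL-13 libraries, whose version and design the header does not state. The aligner, the counting tool and whether counting used strand are not given in the sources used here; the genome build was mm10 per the submitters' processing notes. Per the file headers the table was limited to genes with a corrected p below 1 in that comparison. Each row had at least 1 count over the untreated and IL-13 libraries, so genes seen only with butyrate are not covered, while 1019 rows had no count in any butyrate library.

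The table held 18092 rows, which became 18068 genes after the rows of 23 genes with several were summed. Of the rows, 17799 (98.4%) had an identifier in the GENCODE annotation used for current symbols, and 1837 carried an older symbol. Coordinates are printed as the deposited table gives them. There were 0 mitochondrial rows. Library totals ran from 13867982 to 24294456 counts. Intervals on count ratios, at 95%, cover counting error only, and a group with no count was set to a floor of 3 counts.

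Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (glmQLFit, robust) with TMM normalisation and filterByExpr, which kept 13750 genes and removed 4318. All 12 libraries entered a single fit with a coefficient per group and no replicate block. The biological coefficient of variation was 10.2% with 8 residual degrees of freedom. The 5 comparisons were IL-13 over untreated, butyrate over untreated, both agents over IL-13, both agents over butyrate, and the interaction, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05.

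The 23 gene lists were those of tuft, goblet, Paneth, stem, absorptive and enteroendocrine cells, the IL-13 and STAT6 response, proliferation, bile acid handling, fatty acid oxidation and ketogenesis, butyrate sensing with transport and histone deacetylases, cholesterol synthesis, the unfolded protein response, the p53 response, antimicrobial and acute phase genes, MHC class II, the interferon response, regenerative epithelium, neuronal genes, and mesenchymal, immune, endothelial and glial cells. The 20 with at least 5 tested members were tested with camera (limma 3.58.1, log CPM with a prior count of 2, preset correlation 0.01), and its p was adjusted over 100 tests, 20 lists in 5 comparisons; the mesenchymal, immune and endothelial lists were only counted. The preset treats the genes of every list as equally and weakly correlated, whereas the estimated correlation is taken from the residuals of each list. fry tests whether the genes of a list move on balance one way and does not compare them with other genes.

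Alternatives were RLE scaling, DESeq2 1.42.0, no filter, a filter at a mean of 50 counts, a fit of only the groups compared, a replicate block, each library left out in turn, and for lists also the estimated correlation and fry. After the data were seen, thinning of all libraries to the lowest total and leaving out butyrate replicate 2 and butyrate + IL-13 replicate 3, the libraries highest in Lars2, were added. Named genes were, per comparison and direction, up to 8 called genes with the largest fold change and a mean of at least 50 counts whose groups did not overlap (not asked of the interaction), the 4 members with the smallest adjusted p of each list that was called or had a called member, and a set of fixed genes; the text prints some from the top of each order, and some named genes are not reported here. Among the first, genes with a predicted-gene or clone symbol were skipped. Lars2, Ptprc, the Hist1h genes, and Areg with butyrate over IL-13, Oxct1 with butyrate and Slc10a2 with IL-13 over butyrate were chosen after their values were seen.

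The test was tried on simulated counts for 13587 genes. For IL-13 over untreated it recovered 67.2%, 88.1% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold and called 6 unchanged ones; with nothing changed for butyrate over untreated edgeR called 0. For the interaction it recovered 34.3%, 76.1% and 93.9% and called 8 unchanged ones. For IL-13 with 13557 simulated genes, camera called a list of 25 raised 1.5-fold and 0 of 40 unchanged. Error on correlated lists was not tested. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Reads were not analysed here.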

Results

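Gene expression was measured in enteroids, cultures of intestinal epithelium grown here from the ileum of C57Bl/6 mice, by directional sequencing of poly(A) RNA. The 12 libraries fell into 4 groups of 3: untreated enteroids, enteroids given butyrate at 1 mM for 48 h, enteroids given IL-13 at 20 ng/mL for 72 h, and enteroids given both. Butyrate is a short-chain fatty acid that gut bacteria release from fibre and that inhibits histone deacetylases. IL-13 is a cytokine of type 2 immunity that acts on epithelial cells through the transcription factor STAT6. The order in which the 2 agents were added is not given in the sources used here. Library totals ran from 16303915 to 22558599 counts in untreated enteroids, 17006538 to 24294456 with butyrate, 14239405 to 15008598 with IL-13 and 13867982 to 15618074 with both, so the groups given IL-13 were the shallower ones.

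Every pair of replicates differed by more than sampling noise (chi-square per degree of freedom from 3.92 to 37.88), so all 12 libraries were counted as separate samples. The labels do not say whether the replicates came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. On the first principal component of log CPM, which held 58% of the variance, the 6 libraries without IL-13 lay between -53.2 and -29.7 and the 6 with IL-13 between 21.2 and 65.1. On the second, with 16.2%, the 6 libraries with butyrate lay between -28.7 and -12.2 and the 6 without between 4.5 and 36.8. Levels below are counts scaled by TMM-normalised library size (CPM), as mean ± SD with n = 3 libraries per group, and fold changes are given as log2 ± standard error. Statements on which genes rose or fell most cover called genes with a mean of at least 50 counts whose groups did not overlap, predicted genes left out.

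IL-13 was first compared with untreated enteroids, to ask what the cytokine changes on its own. Some of the genes that rose most were nearly silent without it. Gsdmc2, Gsdmc3 and Gsdmc4, which encode gasdermin C proteins and lie next to each other on chromosome 15 (from 63824346 to 63902936, mm10), went from 0.825 ± 0.166, 0.11 ± 0.0954 and 1.72 ± 0.24 CPM to 727 ± 108, 155 ± 18.1 and 1432 ± 237 CPM. Pla2g4c, a cytosolic phospholipase A2 gene on chromosome 7 (13324655 to 13360672), rose from 2.16 ± 0.229 to 1528 ± 322 CPM (log2 fold change 9.45 ± 0.33, edgeR adjusted p = 2.4e-13). Among the genes that fell most, Dmbt1, a scavenger receptor of mucosal surfaces, went from 214 ± 18.4 to 10.6 ± 4.99 CPM and Zg16, a lectin-like protein of goblet cell granules, from 1075 ± 267 to 80.03 ± 20 CPM.

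In all, 5977 of 13750 genes tested were called at an edgeR adjusted p under 0.05, 2997 of them higher and 2980 lower with IL-13, and 1389 by at least 2-fold. Chil4, a chitinase-like gene, had no count in untreated enteroids; at a floor of 3 counts over the group it was at least 239-fold higher with IL-13. Slc28a1, a nucleoside transporter, and Apol7d had 1 to 3 counts there, which gives count ratios of 317 (95% counting interval 108 to 1540) and 275 (75.7 to 2280). Wfdc16 (log2 fold change -4.71 ± 0.51) and Cyp2c70 (-3.74 ± 0.38), a cytochrome P450 of bile acid metabolism, were also among the genes that fell most, with edgeR adjusted p of 1.8e-06 and 3.1e-07; without IL-13 replicate 3 Wfdc16 stood at -5.84. Without untreated replicate 1 the fitted log2 fold change of Slc28a1 went from 8.1 to 10.93, without untreated replicate 2 to 7.51, and that of Chil4 from 10.58 to 9.87 without IL-13 replicate 1. The gasdermin C genes are close copies of each other whose reads the counting could have split, so the level of each single one is uncertain; the same holds for the Sprr2a and alpha-defensin genes. The authors' deposited table of this comparison holds 6478 genes with an FDR under 0.05 among those tested here, of which 5763 were called here too, all 5763 in the same direction.

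Among gene lists fixed before the data were examined, that of tuft cells was called higher. Of 32 tested, 25 were higher and 2 lower with IL-13. There were 25 and 2 adjusted over the list alone, and camera gave adjusted p = 3.7e-08 and adjusted p = 0.0802 with an estimated correlation. In all, 54 of 100 list tests were called with camera's preset correlation, and 3 of these held with a correlation estimated for each list, which gave the highest adjusted p of all alternatives for each of the 54. Tuft cells are chemosensory epithelial cells that expand in type 2 responses. Dclk1, a tuft cell kinase (ENSMUSG00000027797, chromosome 3, 55242526 to 55539064), rose from 7.41 ± 1.12 to 27 ± 3.06 CPM (log2 fold change 1.87 ± 0.26, edgeR adjusted p = 1.3e-05). Pou2f3, the transcription factor that tuft cells need, rose from 1.11 ± 0.211 to 6.64 ± 0.817 CPM and Trpm5, their taste-pathway ion channel, from 5.08 ± 1.8 to 13.9 ± 1.33 CPM. Il25, the tuft cell cytokine, had 2 counts over all 12 libraries and was not tested.

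The IL-13 and STAT6 response list, which holds the gasdermin C genes, had 17 of 21 members higher and 1 lower. With 17 and 1 adjusted over the list alone, camera gave adjusted p = 7.55e-11. This call held with an estimated correlation (adjusted p = 0.0276). Duox2 and Duoxa2, an NADPH oxidase and its maturation factor, rose from 43.9 ± 4.98 to 777 ± 29.1 CPM and from 25.4 ± 2.85 to 628 ± 52.7 CPM. Clca1, which the table names Clca3 (ENSMUSG00000028255, chromosome 3, 145004537 to 145032776), a secreted goblet cell protease, rose from 462 ± 71.6 to 1417 ± 88.2 CPM. Il4ra, a receptor chain that IL-13 shares with IL-4, rose from 56.6 ± 0.655 to 119.6 ± 7.68 CPM (edgeR adjusted p = 3.5e-08), and the other chain gene Il13ra1 from 104 ± 0.928 to 136 ± 13.3 CPM (edgeR adjusted p = 0.01, but 0.065 without IL-13 replicate 3, with 9.8e-05 to 0.065 over all alternatives). Retnlb, which is also on the list, had 4 counts, all in IL-13 replicate 1, and was not tested.

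Goblet cell genes went both ways. Of 29 tested, 5 were higher and 11 lower, with Clca1 and the fucosyltransferase Fut2 (15.1 ± 4.01 to 63.2 ± 6.6 CPM) up and Zg16 and the disulfide isomerase Agr2 (167 ± 29.3 to 43.2 ± 4.6 CPM) down. There were 6 and 11 adjusted over the list alone, and camera gave adjusted p = 0.389. Muc2, the main gel-forming mucin, stood at 41.8 ± 15.5 CPM untreated and 44.7 ± 5.32 CPM with IL-13 (edgeR adjusted p = 0.73). Paneth cell genes split likewise, 7 higher and 5 lower of 14: the antimicrobial ribonuclease Ang4 rose from 544 ± 88.1 to 2028 ± 347 CPM while lysozyme, Lyz1, fell from 843 ± 87.2 to 235 ± 51.9 CPM. With 7 and 5 adjusted over the list alone, camera gave adjusted p = 0.41. Of 27 enteroendocrine genes, 5 were higher and 2 lower. There were 5 and 2 adjusted over the list alone, and camera gave adjusted p = 0.532. Their granule gene Chga stood at 156 ± 24.9 CPM untreated and 148 ± 11.1 CPM with IL-13 (edgeR adjusted p = 0.69).

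All 28 proliferation genes tested fell with IL-13, with a median log2 fold change of -1.39. With 28 adjusted over the list alone, camera gave adjusted p = 5.15e-15 and adjusted p = 0.141 with an estimated correlation. Mki67 went from 293 ± 2.06 to 122 ± 30.5 CPM and Aurkb from 83.3 ± 3.37 to 28.4 ± 4.33 CPM, while Cdkn1a, the cell cycle inhibitor p21, rose from 443 ± 6.92 to 1404 ± 92.8 CPM. Stem cell genes fell in 10 of 19 cases and rose in 1. There were 10 and 1 adjusted over the list alone, and camera gave adjusted p = 0.0182 and adjusted p = 0.489 with an estimated correlation. Lgr5 went from 9.17 ± 2 to 1.76 ± 0.955 CPM and Axin2 from 55.5 ± 1.74 to 25.4 ± 1.23 CPM. Of 30 absorptive enterocyte genes, 16 rose and 6 fell, among them the nucleotidase Nt5e (36.3 ± 0.551 to 191 ± 19.3 CPM) and the fatty acid binding protein Fabp2 (43.4 ± 1.7 to 11.7 ± 1.55 CPM). With 17 and 6 adjusted over the list alone, camera gave adjusted p = 0.0182 and adjusted p = 0.622 with an estimated correlation. Alkaline phosphatase, Alpi, was not called in any of the 5 comparisons, with group means from 428 ± 114 to 468 ± 55.2 CPM and edgeR adjusted p from 0.66 to 0.99; without the 2 libraries highest in Lars2 (butyrate replicate 2 and butyrate + IL-13 replicate 3) it was called for both agents over IL-13 (0.04) and over butyrate (0.011). Hdac3, a histone deacetylase, went from 58.7 ± 1.83 to 49.2 ± 0.922 CPM (edgeR adjusted p = 0.021, but 0.085 without untreated replicate 2, 0.05 without IL-13 replicate 1 and 0.073 without IL-13 replicate 2, with 0.0053 to 0.085 over all alternatives).

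Of 5 MHC class II genes tested, Cd74 (1.12 ± 0.488 to 6.87 ± 2.05 CPM), H2-Eb1 and H2-Ab1 rose and none fell. The immune marker Cd68 rose with them, from 2.49 ± 0.127 to 5.19 ± 1.45 CPM, and Ptprc, another, had 1 to 3 counts per library untreated and 4 to 10 with IL-13 and was not tested. There were 3 and 0 adjusted over the list alone, and camera gave adjusted p = 0.047 and adjusted p = 0.264 with an estimated correlation. That call was lost with RLE scaling (camera adjusted p = 0.0501), after thinning all libraries to the lowest total (0.0536), without both libraries highest in Lars2 (0.0619) and without any of 6 single libraries (0.051 to 0.0647): untreated replicate 1, butyrate replicates 2 and 3, IL-13 replicate 1 and butyrate + IL-13 replicates 1 and 3. In the interferon response list, 2 of 23 genes rose and none fell. With 2 and 0 adjusted over the list alone, camera gave adjusted p = 0.258. The 2 were Oasl1 and Irf7. The list was called, as higher, without untreated replicate 2 (camera adjusted p = 0.00782, with 0.00782 to 0.823 over all alternatives).

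Butyrate was then compared with untreated enteroids. Interferon-stimulated genes were among the genes that rose most: Ifi27l2a went from 0.348 ± 0.123 to 7.31 ± 2.33 CPM (log2 fold change 4.37 ± 0.33, edgeR adjusted p = 2.3e-07), Trim30a from 2.82 ± 1.88 to 16.3 ± 2.45 CPM and the antiviral sensor Oas3 from 9.31 ± 4.35 to 47.3 ± 6.06 CPM. Among genes of hormone-secreting cells that fell were Chga (ENSMUSG00000021194, chromosome 12, 102554969 to 102565027), from 156 ± 24.9 to 51.7 ± 8.75 CPM, and Chgb (chromosome 2, 132781278 to 132795079), from 977 ± 146 to 396 ± 45.4 CPM. Without untreated replicate 2 the log2 fold change of Trim30a went from 2.5 to 3.23. Stbd1, a glycogen-binding protein, rose from 3.71 ± 1.32 to 19.6 ± 1.53 CPM. Krt4, a keratin, fell from 19.6 ± 3.56 to 2.85 ± 0.405 CPM, Cyp2c70 from 6.28 ± 0.751 to 0.954 ± 0.316 CPM and the transcription factor Spib from 4.68 ± 0.677 to 1.08 ± 0.517 CPM.

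Of 13750 genes tested, 1086 were called, 707 higher and 379 lower with butyrate, and 292 by at least 2-fold. This count moved with single libraries: it was 559 without untreated replicate 3, 607 without untreated replicate 2 and 624 without butyrate replicate 1. Butyrate replicate 2 also stood apart in Lars2, at 5048 CPM, as did butyrate + IL-13 replicate 3 at 6983 CPM, against 422.8 to 1434 CPM in the other 10 libraries. Without both of them, a choice made after their values were seen, 1183 genes were called.

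In the interferon response list, 21 of 23 genes rose and none fell, with a median log2 fold change of 1.42. There were 22 and 0 adjusted over the list alone, and camera gave adjusted p = 4.35e-22 and adjusted p = 0.0885 with an estimated correlation. Oasl2 went from 26 ± 9.33 to 95.8 ± 15.1 CPM and the regulator Irf7 from 38.6 ± 7.65 to 103 ± 20.7 CPM (edgeR adjusted p = 7.3e-06 and 2e-05). Of 5 MHC class II genes, 3 rose and none fell: H2-Eb1 (1.22 ± 0.488 to 3.23 ± 0.145 CPM), Cd74 (1.12 ± 0.488 to 3.09 ± 0.574 CPM) and H2-Ab1, whose edgeR adjusted p of 0.019 went to 0.092 without untreated replicate 1, 0.052 without butyrate replicate 3 and 0.051 in a fit of only these groups (0.003 to 0.092 over all alternatives). With 4 and 0 adjusted over the list alone, camera gave adjusted p = 0.000152 and adjusted p = 0.0824 with an estimated correlation. Of 4 immune genes tested only Lyz2 rose. It is 1 of 7 markers under 1 CPM untreated, whose sum went from 0.924 ± 0.0734 to 1.68 ± 0.375 CPM.

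Of 27 enteroendocrine genes, 23 fell with butyrate and none rose. There were 24 and 0 adjusted over the list alone, and camera gave adjusted p = 2.8e-19 and adjusted p = 0.0824 with an estimated correlation. Neurog3, the transcription factor that starts enteroendocrine fate, went from 9.17 ± 1.55 to 2.62 ± 0.404 CPM. Tuft cell genes fell in 12 of 32 cases and rose in 1. With 14 and 1 adjusted over the list alone, camera gave adjusted p = 1.1e-08 and adjusted p = 0.0802 with an estimated correlation. Trpm5 went from 5.08 ± 1.8 to 1.94 ± 0.237 CPM (edgeR adjusted p = 0.0039). Dclk1, from 7.41 ± 1.12 to 3.04 ± 1.95 CPM (edgeR adjusted p = 0.012), lost its call without untreated replicate 3 (0.065), without butyrate replicate 2 (0.059), without both Lars2-high libraries (0.054) and in a fit of only these groups (0.07), with 0.0011 to 0.07 over all alternatives; its log2 fold change went from -1.22 to -1.81 without butyrate replicate 1. Pou2f3, from 1.11 ± 0.211 to 0.27 ± 0.234 CPM (edgeR adjusted p = 0.016), lost it without untreated replicate 2 (0.071), untreated replicate 3 (0.051) or butyrate replicate 1 (0.082), with 0.00087 to 0.082 over all alternatives, and its log2 fold change went from -2 to -2.74 without butyrate replicate 2. Goblet cell genes fell in 11 of 29 cases and none rose, among them Clca1, from 462 ± 71.6 to 292 ± 41.2 CPM, and Atoh1, the transcription factor of secretory fate, from 57.9 ± 7.93 to 36.7 ± 3.31 CPM. There were 16 and 0 adjusted over the list alone, and camera gave adjusted p = 3.47e-07 and adjusted p = 0.267 with an estimated correlation.

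Lyz1 rose with butyrate from 843 ± 87.2 to 2101 ± 234 CPM (log2 fold change 1.32 ± 0.16, edgeR adjusted p = 4e-05) and Lgr5, the stem cell receptor, from 9.17 ± 2 to 26.4 ± 6.12 CPM, whereas Olfm4, another stem cell gene, fell from 27.1 ± 2.83 to 6.89 ± 2.45 CPM. Their lists moved less evenly. Of 14 Paneth cell genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0497, adjusted p = 0.67 with an estimated correlation), a call that fry (adjusted p = 0.28), RLE scaling (0.0529), leaving out both Lars2-high libraries (0.0717) and leaving out untreated replicate 1 (0.492), butyrate replicate 1 (0.285) or 2 (0.0849) or butyrate + IL-13 replicate 1 (0.054) or 2 (0.058) each ended. Of 19 stem cell genes 2 rose and 3 fell. With 2 and 4 adjusted over the list alone, camera gave adjusted p = 0.417, and 0.0178 (lower) without both Lars2-high libraries, with 0.0178 to 0.951 over all alternatives. Of 28 proliferation genes edgeR called 0 alone (0 adjusted over the list alone; 9 lower at an unadjusted p under 0.05, and 4 lower in DESeq2), though the list as a whole lay lower, with a median log2 fold change of -0.23 (camera adjusted p = 0.000538, adjusted p = 0.436 with an estimated correlation, fry adjusted p = 0.121). Mki67 stood at 293 ± 2.06 and 286 ± 36.6 CPM. Of 30 absorptive enterocyte genes 13 rose and 1 fell, such as the glucose transporter Slc2a2 (327 ± 11.4 to 468 ± 17 CPM). There were 18 and 1 adjusted over the list alone, and camera gave adjusted p = 1.78e-08 and adjusted p = 0.264 with an estimated correlation. In the IL-13 and STAT6 response list 1 gene rose and 2 fell of 21. With 1 and 2 adjusted over the list alone, camera gave adjusted p = 0.727. Cdkn1a rose from 443 ± 6.92 to 695 ± 34.8 CPM (edgeR adjusted p = 2.1e-05).

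**Figure D1:**
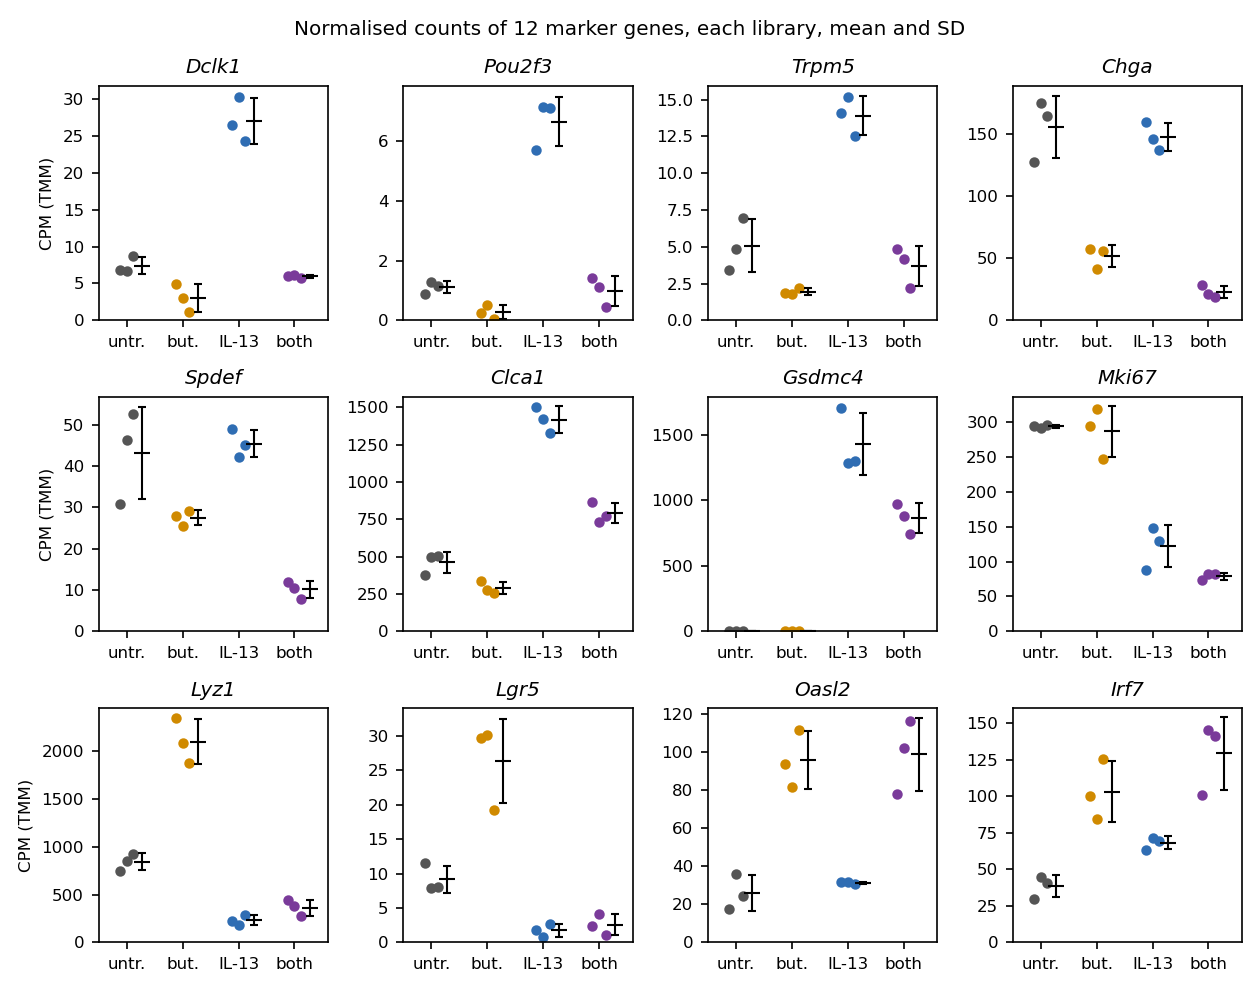
Normalised counts (CPM, linear axes from 0) of 12 genes in each of the 12 libraries, by group: untreated (untr.), butyrate (but.), IL-13 and both agents (both). Points are libraries, and the black marks give the mean and SD of 3; Dclk1 averages 27 CPM with IL-13 and 5.95 CPM with both agents, while Oasl2 averages 95.8 and 98.8 CPM in the groups given butyrate.

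Both agents were then compared with IL-13 alone. The tuft, enteroendocrine and goblet cell lists were called lower, of which the tuft list held with an estimated correlation (camera adjusted p = 0.0276) and the others did not (0.0802 and 0.141). Dclk1 went from 27 ± 3.06 CPM with IL-13 to 5.95 ± 0.22 CPM with both (log2 fold change -2.18 ± 0.27, edgeR adjusted p = 2.7e-05), Pou2f3 from 6.64 ± 0.817 to 0.992 ± 0.504 CPM, Chga from 148 ± 11.1 to 22.8 ± 4.93 CPM and the goblet cell transcription factor Spdef from 45.4 ± 3.33 to 10.1 ± 2.09 CPM. Interferon-stimulated genes were again among the genes that rose most: Ifi27l2a went from 1.18 ± 0.271 to 7.74 ± 1.55 CPM and Rsad2, the antiviral enzyme viperin, from 3.61 ± 0.502 to 17.6 ± 6.87 CPM. So were others: Azin2, an antizyme inhibitor, rose from 3.16 ± 0.29 to 16.9 ± 4.82 CPM.

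Of 13750 genes tested, 2912 were called, 1355 higher and 1557 lower with both agents than with IL-13 alone; at 2-fold or more, 166 were higher and 583 lower. Without butyrate + IL-13 replicate 3, 1 of the libraries high in Lars2, 1935 genes were called, and without both such libraries 2387. More genes were higher than lower with RLE scaling (1551 and 1441), in DESeq2 (1764 and 1607), in a fit of only these groups (1408 and 1375), and without butyrate + IL-13 replicate 1 (1446 and 1364) or 3 (977 and 958). Among called genes with a mean of at least 50 counts, those that fell most were Nrep (log2 fold change -3.91 ± 0.48, and -4.62 without butyrate + IL-13 replicate 2), A4gnt, a mucin glycosyltransferase (-3.66 ± 0.35), Prelp, a matrix proteoglycan (51.9 ± 2.3 CPM untreated, 27.2 ± 11.4 CPM with IL-13 and 2.59 ± 1.53 CPM with both), and Olfm4 (21.5 ± 2.38 to 2.17 ± 0.391 CPM).

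Of 32 tuft cell genes, 25 fell and none rose, with a median log2 fold change of -2. There were 27 and 0 adjusted over the list alone, and camera gave adjusted p = 2.15e-15. This call held with an estimated correlation (adjusted p = 0.0276). Trpm5 went from 13.9 ± 1.33 to 3.72 ± 1.36 CPM and Spib from 20.7 ± 1.89 to 2.86 ± 0.983 CPM. All 27 enteroendocrine genes fell, with a median log2 fold change of -2.15; Chgb went from 1005 ± 43.4 to 186 ± 57.2 CPM and Tph1, which makes serotonin, from 29.7 ± 1.96 to 5.05 ± 2.41 CPM. With 27 adjusted over the list alone, camera gave adjusted p = 7.58e-22 and adjusted p = 0.0802 with an estimated correlation. Goblet cell genes fell in 24 of 29 cases and 1 rose. There were 24 and 1 adjusted over the list alone, and camera gave adjusted p = 2.99e-13 and adjusted p = 0.141 with an estimated correlation. Atoh1 went from 37 ± 4.55 to 10.6 ± 1.35 CPM, Agr2 (ENSMUSG00000020581, chromosome 12, 35992907 to 36004087) from 43.2 ± 4.6 to 9.13 ± 2.94 CPM and Muc2 from 44.7 ± 5.32 to 19.8 ± 3.02 CPM.

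Genes of the IL-13 and STAT6 response did not move as a group: 2 of 21 rose and 6 fell. With 7 and 6 adjusted over the list alone, camera gave adjusted p = 0.694. Its median log2 fold change was 0.05 and its mean -0.16; median, mean and test differed in sign or lay at 0 in 14 of the 100 list tests, of which camera called 0 (0 also at an unadjusted p under 0.05) and fry 2. Duox2 rose further, from 777 ± 29.1 to 1034 ± 65.5 CPM. Clca1 fell from 1417 ± 88.2 to 790.5 ± 67.4 CPM, Gsdmc2 from 727 ± 108 to 375 ± 45.3 CPM and Ang4 from 2028 ± 347 to 883 ± 160 CPM. Il4ra stood at 119.6 ± 7.68 and 135 ± 4.18 CPM (edgeR adjusted p = 0.19). Paneth cell genes fell in 7 of 14 cases and rose in 2. There were 9 and 2 adjusted over the list alone, and camera gave adjusted p = 0.0051 and adjusted p = 0.489 with an estimated correlation. Lyz1, from 235 ± 51.9 to 363 ± 85.5 CPM, was among the 2 that rose (edgeR adjusted p = 0.0089, but 0.053 with no filter, 0.11 in a fit of only these groups and 0.058 without IL-13 replicate 2, with 9e-04 to 0.11 over all alternatives).

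In the interferon response list 20 of 23 genes rose and none fell, with a median log2 fold change of 1.41; Oasl2 went from 31.4 ± 0.492 to 98.8 ± 19.3 CPM and Stat2 from 40.2 ± 5.47 to 82.8 ± 15.9 CPM. With 22 and 0 adjusted over the list alone, camera gave adjusted p = 2.02e-13 and adjusted p = 0.152 with an estimated correlation. Of 5 MHC class II genes 3 rose, among them Cd74 (6.87 ± 2.05 to 15.2 ± 3.29 CPM). There were 4 adjusted over the list alone, and camera gave adjusted p = 0.00458 and adjusted p = 0.141 with an estimated correlation. Proliferation genes fell in 20 of 28 cases. With 23 adjusted over the list alone, camera gave adjusted p = 7.55e-11 and adjusted p = 0.199 with an estimated correlation. The replication factor Mcm2 went from 33.8 ± 4.63 to 12.8 ± 2.67 CPM and Mki67 from 122 ± 30.5 to 78.9 ± 4.99 CPM. Of 19 stem cell genes 9 fell and 2 rose, and Lgr5 stood at 1.76 ± 0.955 and 2.54 ± 1.53 CPM (edgeR adjusted p = 0.45). There were 9 and 2 adjusted over the list alone, and camera gave adjusted p = 0.00568 and adjusted p = 0.425 with an estimated correlation. Of 30 absorptive enterocyte genes 12 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.00287, adjusted p = 0.489 with an estimated correlation), a call that ended with fry (adjusted p = 0.0912), without butyrate + IL-13 replicate 3 (0.105) and without both Lars2-high libraries (0.0904).

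Most genes that butyrate changed without IL-13 changed in the same direction with it. Of the 1086 and 2912 called, 779 were called in both, 500 higher in both, 273 lower in both and 6 in opposite directions; independent lists of these sizes would share 70 higher and 43 lower. The comparisons share no library. Across all genes the log2 fold changes had a Spearman correlation of 0.6, with genes not being independent replicates. The 773 genes called in the same direction became 435 without untreated replicate 3, 462 without untreated replicate 2 and 481 without butyrate replicate 1, and the Spearman correlation 0.38 with no filter on low counts.

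**Figure D2:**
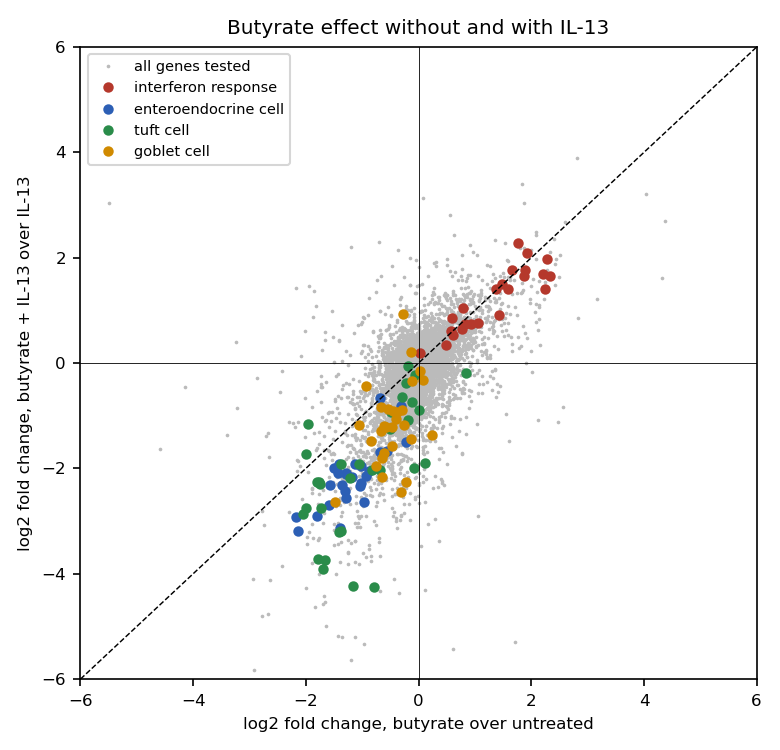
Log2 fold change of each gene tested for butyrate over untreated (horizontal axis) and for butyrate + IL-13 over IL-13 (vertical axis), with members of 4 gene lists coloured and the dashed line marking equal change; 2 genes lie outside the plotted range. Interferon response genes sit at the upper right, with medians of 1.42 and 1.41, and enteroendocrine genes below the line, with medians of -1.29 and -2.15.

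IL-13 given on top of butyrate was compared with butyrate alone. Gsdmc3, Gsdmc2 and Gsdmc4 rose from 0.107 ± 0.153, 0.603 ± 0.493 and 1.77 ± 1.39 CPM to 106 ± 13.6, 375 ± 45.3 and 865 ± 114 CPM, and Pla2g4c from 2.55 ± 1.86 to 1580 ± 359 CPM (log2 fold change 9.36 ± 0.33, edgeR adjusted p = 2.3e-13). Without butyrate replicate 3 their log2 fold changes went from 10, 9.4, 9.04 and 9.36 to 11.82, 10.19, 9.79 and 10.07. Capn13, a calpain protease, rose from 1.83 ± 0.412 to 134 ± 10.6 CPM and Fn1 from 1.34 ± 0.497 to 95.1 ± 17.6 CPM. Rgcc, a cell cycle regulator (4.95 ± 0.592 to 0.183 ± 0.0952 CPM), the defensin gene Defa29 (4.8 ± 0.7 to 0.179 ± 0.0863 CPM), Cyp2e1 (10.3 ± 3.12 to 0.565 ± 0.237 CPM) and Agr2 (144 ± 18.5 to 9.13 ± 2.94 CPM) fell most. In all 6564 of 13750 genes were called, 3144 higher and 3420 lower, and 1774 by at least 2-fold. More were higher than lower with RLE scaling (3374 and 3185), in DESeq2 (3449 and 3284), in a fit of only these groups (2672 and 2660) and without butyrate + IL-13 replicate 1 (3259 and 3049) or 3 (2930 and 2753).

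The IL-13 and STAT6 response list had 16 of 21 members higher and 1 lower. With 16 and 1 adjusted over the list alone, camera gave adjusted p = 9.15e-10. The call held with an estimated correlation (adjusted p = 0.0276). Duox2 rose from 36.8 ± 3.48 to 1034 ± 65.5 CPM, Clca1 from 292 ± 41.2 to 790.5 ± 67.4 CPM and Il4ra from 67.9 ± 9.02 to 135 ± 4.18 CPM. Tuft cell genes rose in 13 of 32 cases and fell in 2. There were 13 and 2 adjusted over the list alone, and camera gave adjusted p = 0.0129 and adjusted p = 0.294 with an estimated correlation. Dclk1, from 3.04 ± 1.95 to 5.95 ± 0.22 CPM (edgeR adjusted p = 0.021), lost its call with no filter (0.05), in a fit of only these groups (0.063), without butyrate replicate 2 (0.066) or butyrate + IL-13 replicate 2 (0.05) and without both Lars2-high libraries (0.094), with 0.00068 to 0.094 over all alternatives. Pou2f3 rose from 0.27 ± 0.234 to 0.992 ± 0.504 CPM (edgeR adjusted p = 0.0096, but 0.053 without butyrate + IL-13 replicate 1, with 0.00036 to 0.053 over all alternatives). Without butyrate replicate 1 the log2 fold change of Dclk1 went from 0.91 to 1.5, and without butyrate replicate 2 that of Pou2f3 from 1.83 to 2.56.

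Goblet cell genes fell in 20 of 29 cases and rose in 3. With 20 and 4 adjusted over the list alone, camera gave adjusted p = 0.00036 and adjusted p = 0.408 with an estimated correlation. Fut2 was among the 3, going from 12.3 ± 2.52 to 120.4 ± 2.94 CPM. Enteroendocrine genes fell in 17 of 27 cases and 1 rose, the processing enzyme Cpe. There were 19 and 1 adjusted over the list alone, and camera gave adjusted p = 0.00175 and adjusted p = 0.425 with an estimated correlation. Chga went from 51.7 ± 8.75 to 22.8 ± 4.93 CPM. All 28 proliferation genes fell, among them Mcm2, from 73 ± 1.45 to 12.8 ± 2.67 CPM, and Mki67, from 286 ± 36.6 to 78.9 ± 4.99 CPM. With 28 adjusted over the list alone, camera gave adjusted p = 7.92e-16 and adjusted p = 0.141 with an estimated correlation. Stem cell genes fell in 13 of 19 cases and 1 rose, with Lgr5 going from 26.4 ± 6.12 to 2.54 ± 1.53 CPM. There were 13 and 1 adjusted over the list alone, and camera gave adjusted p = 0.000148 and adjusted p = 0.292 with an estimated correlation. Paneth cell genes were 4 higher and 8 lower of 14, with Lyz1 down from 2101 ± 234 to 363 ± 85.5 CPM. With 4 and 8 adjusted over the list alone, camera gave adjusted p = 0.266. Absorptive enterocyte genes were 14 higher and 7 lower of 30 (14 and 7 adjusted over the list alone; camera adjusted p = 0.16), interferon response genes 2 higher and 1 lower of 23 (1 and 0 adjusted over the list alone; camera adjusted p = 0.588) and MHC class II genes 3 higher of 5 (3 adjusted over the list alone; camera adjusted p = 0.0641). The MHC class II list was called, as higher, by fry (adjusted p = 0.00151) and by camera without untreated replicate 1 (0.0428) or 2 (0.0477) or butyrate + IL-13 replicate 3 (0.0377), with 0.00151 to 0.292 over all alternatives.

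The IL-13 comparisons called 5977 genes without butyrate and 6564 with it; 4853 were called in both, 2449 higher in both, 2392 lower in both and 12 in opposite directions, where independent lists would share 685 and 741. The Spearman correlation of the log2 fold changes across genes was 0.82 (0.55 with no filter on low counts), and no library is shared.

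Markers of cells that a purely epithelial culture should lack moved in part. Fn1, which encodes fibronectin and stood on the mesenchymal list (chromosome 1, 71585523 to 71653171), rose with IL-13 from 1.74 ± 0.279 to 106 ± 14.5 CPM, and the immune gene Cd68 from 2.49 ± 0.127 to 5.19 ± 1.45 CPM. Both also rose with IL-13 given with butyrate. Summed over the other 13 mesenchymal genes in the table, the level was 9.09 ± 1.57 CPM untreated and 6.67 ± 0.624 CPM with IL-13. Of the 4 mesenchymal, 4 immune, 3 endothelial and 5 glial genes tested, IL-13 over untreated also raised Vwf (log2 fold change 2.05 ± 0.53), Pecam1 (1.23 ± 0.46) and Foxd3 (2.03 ± 0.35) and lowered Pdgfrb (-1.19 ± 0.29) and Erbb3 (-0.35 ± 0.09; glial list camera adjusted p = 0.858). Butyrate over untreated raised Lyz2 (2.01 ± 0.6) and, with IL-13 present, Pdgfrb (0.98 ± 0.31), Entpd2 (0.69 ± 0.11) and Erbb3 (0.27 ± 0.09) while Vim fell (-2.02 ± 0.61; glial list camera adjusted p = 0.4 and 0.322). fry called the glial list higher in the latter (adjusted p = 0.0152). IL-13 over butyrate raised Esam (0.75 ± 0.23), Vwf (1.59 ± 0.6), Entpd2 (0.63 ± 0.1) and Foxd3 (1.42 ± 0.33) and lowered Vim (-1.91 ± 0.6) and Lyz2 (-2.49 ± 0.72; glial list camera adjusted p = 0.858). For the genes named here the calls adjusted over the list alone were the same, except that Esam was also called lower with butyrate. Where edgeR called 0 of the endothelial, glial and mesenchymal genes with butyrate over untreated, the unadjusted p was under 0.05 for 1, 1 and 0 of them, and DESeq2 called 0; for the immune and endothelial genes with both agents over IL-13 these counts were 0.

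Several of these calls ended with 1 library fewer, some at nearly the same fold. By edgeR adjusted p, Pecam1 lost its call without any of the 6 untreated and IL-13 libraries (0.076 to 0.095, at log2 fold changes of 1.19 to 1.27), with no filter (0.067) and with a replicate block (0.053), and ranged from 0.013 to 0.095 over all alternatives. Lyz2 with butyrate lost it without any of 10 libraries (0.051 to 0.17: all but butyrate replicate 3 and butyrate + IL-13 replicate 3), with no filter (0.076), with the block (0.061), in DESeq2 (0.059), in a fit of only these groups (0.088), after thinning (0.12) and without both Lars2-high libraries (0.093), with 0.039 to 0.17 over all; its log2 fold change was 1.37 without untreated replicate 2. With both agents over IL-13, Vim lost it without IL-13 replicate 2 (0.085) or 3 (0.059), butyrate + IL-13 replicate 1 (0.06) or 3 (0.097) or both Lars2-high libraries (0.083), with 0.0049 to 0.097 over all, and its log2 fold change was -3.13 without butyrate + IL-13 replicate 2 and -1.4 without replicate 3. In the same comparison Pdgfrb lost it in a fit of only these groups (0.055) and without IL-13 replicate 1 (0.098) or 2 (0.085) or butyrate + IL-13 replicate 1 (0.096) or 2 (0.088), at log2 fold changes of 0.84 to 0.99, with 0.01 to 0.098 over all. Erbb3 lost it in a fit of only these groups (0.05) and without untreated replicate 2 (0.057) or 3 (0.052), butyrate replicate 1 (0.054), IL-13 replicate 1 (0.17) or 3 (0.068), butyrate + IL-13 replicate 3 (0.17) or both Lars2-high libraries (0.18), with 0.011 to 0.18 over all. With IL-13 over butyrate, Esam lost it without butyrate + IL-13 replicate 2 (0.058, with 0.0043 to 0.058 over all) and Lyz2 without butyrate + IL-13 replicate 3 (0.051) or both Lars2-high libraries (0.077, with 0.0017 to 0.077 over all). Vim lost it there without butyrate replicate 1 (0.082) or butyrate + IL-13 replicate 3 (0.063), with 0.0034 to 0.082 over all, and its log2 fold change was -3.02 without butyrate + IL-13 replicate 2 and -1.28 without replicate 3. Vwf lost it without butyrate replicate 1 (0.084) or 2 (0.087), butyrate + IL-13 replicate 2 (0.22) or 3 (0.097) or both Lars2-high libraries (0.16), with 0.0042 to 0.22 over all.

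**Figure D3:**
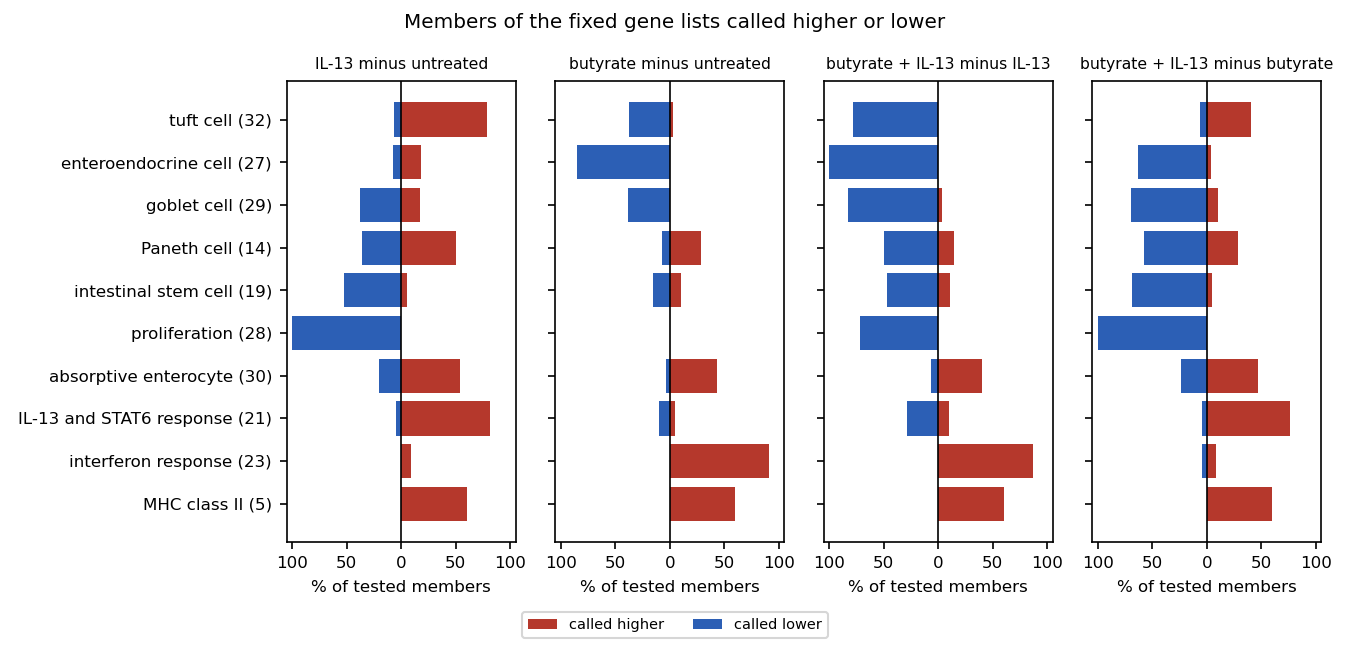
Share of the tested members of 10 gene lists (number tested in brackets) called higher (red, to the right) or lower (blue, to the left) in each of the 4 comparisons of pairs of groups, as a percentage of members tested. Of 32 tuft cell genes, 25 were higher with IL-13 over untreated and 25 lower with butyrate + IL-13 over IL-13, and all 28 proliferation genes were lower in both comparisons that add IL-13.

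The interaction is the log2 fold change of IL-13 given with butyrate minus that of IL-13 without it. The goblet cell genes Agr2 (-2.03 ± 0.24, edgeR adjusted p = 0.00051), Rep15, a secretory vesicle protein (-2.13 ± 0.26, 0.00065), Spdef (-1.51 ± 0.24, 0.0049) and Atoh1 (-1.15 ± 0.18, 0.0052) were lower with both agents than the effects of each add up to on the log2 scale: Spdef stood at 43.1 ± 11.2 CPM untreated, 27.5 ± 1.85 with butyrate, 45.4 ± 3.33 with IL-13 and 10.1 ± 2.09 with both. Tgfbi, a secreted matrix protein, was higher than the sum (1.19 ± 0.11, edgeR adjusted p = 6.4e-05), with 49.3 ± 1.66, 43.6 ± 2.96, 523 ± 33.3 and 1055 ± 56.1 CPM in the same order. Of 13750 genes tested, 119 were called, 35 higher and 84 lower than additive, and 74 by at least 2-fold.

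Among called genes with a mean of at least 50 counts, predicted genes left out, the most negative interaction was that of A4gnt (-2.81 ± 0.46, edgeR adjusted p = 0.0059), followed by the calcium channel subunit Cacna2d1 (-2.71 ± 0.47) and the G protein regulator Rgs4 (-2.51 ± 0.47). The most positive among these were Plekhd1 (1.67 ± 0.34), the keratin Krt84 (1.44 ± 0.28), Capn13 (1.23 ± 0.19) and Fut2 (1.21 ± 0.23). Fut2 lost its call without untreated replicate 2 (edgeR adjusted p = 0.052, with 8.2e-05 to 0.052 over all alternatives), Plekhd1 when any of 7 libraries was left out (0.052 to 0.069: untreated replicates 1 and 3, butyrate replicate 1, IL-13 replicates 1 and 2, butyrate + IL-13 replicates 2 and 3) and Krt84 when any of 5 was (0.052 to 0.087: untreated replicates 2 and 3, butyrate replicate 1, IL-13 replicates 1 and 2). Without both Lars2-high libraries Plekhd1 and Krt84 stood at edgeR adjusted p of 0.068 and 0.061, and after thinning Krt84 at 0.09; over all alternatives they ran from 0.00054 to 0.069 and from 0.00043 to 0.09.

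Of 29 goblet cell genes 6 were lower and 1 higher than additive. There were 12 and 1 adjusted over the list alone, and camera gave adjusted p = 1.72e-10 and adjusted p = 0.187 with an estimated correlation. Of 27 enteroendocrine genes 3 were lower, Chga among them (-1.1 ± 0.21, edgeR adjusted p = 0.015, but 0.056 without butyrate replicate 1 and 0.052 without IL-13 replicate 1, with 0.00023 to 0.056 over all alternatives). With 19 adjusted over the list alone, camera gave adjusted p = 3.09e-12 and adjusted p = 0.141 with an estimated correlation. Of 14 Paneth cell genes 5 were lower, including Ang4 (-1.34 ± 0.21) and Kit (-1.45 ± 0.26). There were 10 adjusted over the list alone, and camera gave adjusted p = 1.61e-09 and adjusted p = 0.209 with an estimated correlation. Of 28 proliferation genes 5 were lower (14 adjusted over the list alone; camera adjusted p = 1.41e-09, adjusted p = 0.227 with an estimated correlation), Mcm2 first (-1.06 ± 0.17, edgeR adjusted p = 0.0059), and of 19 stem cell genes 2 (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000225, adjusted p = 0.3 with an estimated correlation, fry adjusted p = 0.0597), with the ion transporter Slc12a2 at -1.17 ± 0.19.

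Of 32 tuft cell genes edgeR called 0 in the interaction (12 lower at an unadjusted p under 0.05, 7 lower adjusted over the list alone, and 3 lower in DESeq2), while the list lay lower than additive, with a median of -0.88 (camera adjusted p = 2.24e-10, adjusted p = 0.0746 with an estimated correlation). Dclk1 had -0.96 ± 0.4 (edgeR adjusted p = 0.38, but 0.013 without butyrate replicate 3, with 0.013 to 0.89 over all alternatives). In the IL-13 and STAT6 response list 2 genes were higher, Duoxa2 (0.9 ± 0.15) and Duox2, and 1 lower, Ang4, of 21. With 4 and 2 adjusted over the list alone, camera gave adjusted p = 0.498. Duox2 had 0.67 ± 0.13 (edgeR adjusted p = 0.019), but 0.08 without untreated replicate 2, 0.059 and 0.057 without IL-13 replicates 1 and 2 and 0.056 without butyrate + IL-13 replicate 3, with 0.00019 to 0.08 over all alternatives. The median of this list was -0.09 and its mean -0.17, while camera's direction was up. Of 23 interferon response genes edgeR called 0 (1 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 in DESeq2; camera adjusted p = 0.385). Of 30 absorptive enterocyte genes it called 0 (1 higher and 5 lower unadjusted, 0 over the list alone and 0 in DESeq2; camera adjusted p = 0.0629) and of 5 MHC class II genes 0 (0 in each of these counts; camera adjusted p = 0.86, with a median of -0.17 and a mean of 0). The absorptive list was called, as lower, without untreated replicate 1 (camera adjusted p = 0.0298), butyrate replicate 2 (0.0191), IL-13 replicate 3 (0.0476) or butyrate + IL-13 replicate 3 (1.25e-05) and without both Lars2-high libraries (8.33e-07), with 8.33e-07 to 0.692 over all alternatives. The interferon list was called, as lower, without untreated replicate 2 (camera adjusted p = 0.000862) and without both Lars2-high libraries (0.0243), with 0.000862 to 0.895 over all alternatives. Of the markers of mesenchymal, immune, endothelial and glial cells edgeR called 0 (1, 0, 0 and 1 at an unadjusted p under 0.05, with 1 glial gene adjusted over the list alone and 1 in DESeq2; glial list camera adjusted p = 0.518).

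The number of genes in the interaction moved with single libraries and with the tool. It was 55 without untreated replicate 2, 56 without butyrate replicate 1, 64, 68 and 70 without IL-13 replicates 2, 1 and 3, 69 and 76 without untreated replicates 3 and 1, and 70 without butyrate + IL-13 replicate 3, but 182 without butyrate + IL-13 replicate 1 and 213 without butyrate replicate 3. DESeq2 called 276, with 109 higher and 167 lower (39.5% higher, against 29.4%).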

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

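Except for those of GC content and transcript length, the tests of depth, of single libraries and of RNA from other cells given here were chosen after the result they bear on had been seen.

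For 25 genes named in the text the effect of IL-13 differed with butyrate by the test of the interaction itself (edgeR adjusted p under 0.05). Below additive on the log2 scale lay A4gnt (-2.81), Cacna2d1 (-2.71), Rgs4 (-2.51), Rgcc (-2.4), Prelp (-2.21), Rep15 (-2.13), Agr2 (-2.03), Spdef (-1.51), Kit (-1.45), Ang4 (-1.34), Olfm4 (-1.34), Slc12a2 (-1.17), Atoh1 (-1.15), Chgb (-1.13), Chga (-1.1) and Mcm2 (-1.06). Above it lay Pigr (0.45), Duox2 (0.67), Fgf15 (0.85), Duoxa2 (0.9), Tgfbi (1.19), Fut2 (1.21), Capn13 (1.23), Krt84 (1.44) and Plekhd1 (1.67).

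Of these calls, 11 ended when single libraries were left out, and some with other alternatives too, here given with edgeR adjusted p. Rgcc lost its call without untreated replicate 1, 2 or 3, butyrate replicate 1, IL-13 replicate 1 or 3 or butyrate + IL-13 replicate 2 or 3 (0.061 to 0.15, with 0.019 to 0.15 over all alternatives) and without both Lars2-high libraries (0.13). Prelp lost it without any library but IL-13 replicate 1 and butyrate + IL-13 replicate 1 (0.053 to 0.24, with 0.0089 to 0.24 over all), with the replicate block (0.07), with no filter (0.22), in DESeq2 (adjusted p = 0.055) and without both Lars2-high libraries (0.22). Olfm4 lost it without any but butyrate replicate 3 and butyrate + IL-13 replicate 1 (0.06 to 0.16, with 0.0035 to 0.16 over all), with the replicate block (0.06) and without both Lars2-high libraries (0.14). Chgb lost it without untreated replicate 1, any butyrate library, IL-13 replicate 1 or 2 or butyrate + IL-13 replicate 2 (0.056 to 0.14, with 0.00043 to 0.14 over all) and with no filter (0.12). Pigr lost it without any but butyrate replicates 2 and 3 and butyrate + IL-13 replicate 1 (0.061 to 0.12). Plekhd1 lost it without untreated replicate 1 or 3, butyrate replicate 1, IL-13 replicate 1 or 2 or butyrate + IL-13 replicate 2 or 3 (0.052 to 0.069) and without both Lars2-high libraries (0.068), and Krt84 without untreated replicate 2 or 3, butyrate replicate 1 or IL-13 replicate 1 or 2 (0.052 to 0.087), without both Lars2-high libraries (0.061) and after thinning (0.09). Duox2 lost it without untreated replicate 2, IL-13 replicate 1 or 2 or butyrate + IL-13 replicate 3 (0.056 to 0.08), and Fgf15 without untreated replicate 2, butyrate replicate 1 or IL-13 replicate 1 or 2 (0.055 to 0.062). Chga lost it without butyrate replicate 1 (0.056) or IL-13 replicate 1 (0.052), and Fut2 without untreated replicate 2 (0.052).

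The same test across gene lists called 9 in the interaction with camera's preset correlation and 0 with an estimated one. Their median interactions were -1.01 for enteroendocrine, -0.88 for tuft, -0.88 for Paneth, -0.63 for goblet and -0.45 for stem cell genes, -0.48 for proliferation, 0.12 for fatty acid oxidation, 0.28 for cholesterol synthesis and 0.18 for antimicrobial genes. The antimicrobial call ended without IL-13 replicate 2 (camera adjusted p = 0.0791) and butyrate + IL-13 replicate 3 (0.051).

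The first pattern weighed was that enteroendocrine, tuft and goblet cell genes were lower with butyrate, with a median log2 fold change of -0.83 over untreated and -1.91 over IL-13. Thinning all libraries to the lowest total keeps each gene's expected share, so the unchanged medians (-0.83 and -1.91) decide nothing. The group totals overlapped, which argues against depth. Their mean log2 ratio was -0.0314 over untreated (SD between libraries 0.266) and -0.0247 over IL-13 (0.0732). Removing the trend over GC content and transcript length gave medians of -0.79 ± 0.09 and -1.92 ± 0.14 (SE, genes taken as independent). Of 88 members 87 had a value. The trend was too small to account for the pattern, moving members by a median of 0.04 and 0.01. A lower share of these secretory cells under butyrate and lower expression within them both stay open as biological hypotheses, since the counts come from whole cultures. The timing of the agents (48 h and 72 h) may matter too and was not varied.

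The second pattern was the rise of the interferon response list with butyrate, from 499 ± 64.4 to 934 ± 120 CPM summed over its 24 genes. If RNA of immune cells were the source, the 7 immune markers under 1 CPM in untreated enteroids would have risen by at least the same fold. With IL-13 present they did not, going from 1.31 ± 0.368 to 0.925 ± 0.0426 CPM, and the ratio of their fold change to that of the list was 0.396 ± 0.074 (SE), which argues against that source there. Without IL-13 they rose from 0.924 ± 0.0734 to 1.68 ± 0.375 CPM, a ratio of 0.97 ± 0.167. RNA of immune cells is not excluded there, but this rise lay in Lyz2 and was 0.00173 of that of the list in CPM. Nor did 1 library decide the rise of the list. Without untreated replicate 1, the library whose absence left the fewest, 18 members were still called higher over untreated and 18 over IL-13. With all libraries these were 21 and 20. A response of the epithelium to butyrate stays open beside it as a hypothesis.

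The third pattern was the rise of Fn1 with IL-13, from 1.74 ± 0.279 to 106 ± 14.5 CPM. RNA of fibroblasts would bring their other abundant transcripts, yet the other 13 mesenchymal markers summed to 9.09 ± 1.57 CPM untreated and 6.67 ± 0.624 CPM with IL-13, a ratio to the rise of Fn1 of -0.0233, and of -0.0325 with butyrate present. This argues against mesenchymal RNA as the source, and expression of Fn1 by epithelial cells given IL-13 is a hypothesis that these counts leave open.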

How the results depend on the processing

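Thinning to the lowest total and leaving out both Lars2-high libraries were chosen as alternatives after the data had been seen; the other alternatives were planned.

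Of 197 pairs of a named gene and a comparison, 182 were called; 153 of these kept direction and call under every alternative run, 29 lost the call under at least 1 and 0 reversed. Of 54 called list tests, 44 kept the call under every alternative but the estimated correlation, under which 3 did. The number of lists called was then 1 for IL-13, 0 for butyrate, 1 for butyrate over IL-13, 1 for IL-13 over butyrate and 0 for the interaction, while fry called 14 for IL-13. DESeq2 called 276 genes in the interaction, 109 higher and 167 lower, and the cause was not tested. The pseudocount alternative was not run, because the values are counts.

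With 1 library left out in turn, genes called ran from 559 to 1395 for butyrate (370 to 851 higher, 172 to 544 lower), from 1935 to 3451 for butyrate over IL-13 (894 to 1634 higher, 958 to 1817 lower) and from 55 to 213 for the interaction (16 to 81 higher, 36 to 132 lower), and the genes shared by the butyrate effects from 435 to 895. Each such fit has fewer libraries; beyond that the cause was not tested.

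Replicate numbers did not pair the libraries: the deviations of 18 pairs with the same number correlated at -0.15 to 0.1, with 0 above 0.1, and 2 of 12 libraries correlated best with their own number. With the number as a replicate block 5866, 978, 2757, 6447 and 114 genes were called for IL-13, butyrate, butyrate over IL-13, IL-13 over butyrate and the interaction, all within 1.5 times of the counts without the block.

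Directions turned only for results that were not called with all libraries; the cause was not tested. Among lists, by adjusted p, fry turned the IL-13 and STAT6 response with butyrate over IL-13 (0.913) and butyrate sensing in the interaction (0.661). Leaving out both Lars2-high libraries turned the IL-13 and STAT6 response with butyrate (0.983), MHC class II in the interaction (0.984), and interferon response (0.875) and regenerative genes (0.983) with IL-13 over butyrate. Single libraries left out turned others in some cases. Over all 12 left out, the adjusted p ran from 0.776 to 0.948 for antimicrobial genes with IL-13, and with butyrate from 0.0616 to 0.951 for stem cell genes and from 0.354 to 0.958 for cholesterol synthesis. With IL-13 over butyrate it ran from 0.434 to 0.951 for cholesterol synthesis, 0.683 to 0.974 for regenerative genes and 0.807 to 0.94 for neuronal genes. In the interaction it ran from 0.471 to 0.97 for bile acid handling, 0.548 to 0.999 for butyrate sensing, 0.389 to 0.975 for the unfolded protein response, 0.493 to 0.963 for MHC class II and 0.000862 to 0.895 for interferon response. Among genes, by log2 fold change, Cd68 turned with butyrate after thinning (-0.07). With single libraries left out, 5 genes turned with IL-13: Alpi (-0.09 to 0.08), Chga (-0.2 to 0.02), Esam (-0.07 to 0.34), Lyz2 (-0.95 to 0.24) and Muc2 (-0.18 to 0.29). Mki67 turned with butyrate (-0.12 to 0.06), and Fn1 (-0.24 to 0.02) and Lgr5 (-0.04 to 0.94) with butyrate over IL-13.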

Other observations

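The splits of the libraries given last, thinning, and leaving out both Lars2-high libraries were chosen as tests after the results they bear on had been seen.

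Both chains of a bile acid transporter rose with both agents. Slc51b, a chain of the transporter that moves bile acids from enterocytes towards the blood, stood at 6.89 ± 0.173 CPM untreated, 10.8 ± 1.18 CPM with butyrate, 30.8 ± 3.72 CPM with IL-13 and 52.8 ± 5.68 CPM with both. The other chain gene, Slc51a, stood at 19 ± 0.662, 28 ± 3.12, 52.5 ± 4.17 and 71.3 ± 5.96 CPM in the same order, and both rose in all 4 comparisons of pairs of groups (edgeR adjusted p from 7.73e-11 to 0.0047). Of 8 genes of ileal bile acid handling, IL-13 raised 5 and butyrate 3. With the other agent present, butyrate raised 4, and IL-13 raised 6 and lowered 1, Slc10a2. In the order IL-13, butyrate, butyrate over IL-13 and IL-13 over butyrate, 6, 6, 5 and 6 were higher and 0, 0, 1 and 1 lower adjusted over the list alone. The list had camera adjusted p = 0.00205, 9.95e-05, 0.0238 and 0.00568, and adjusted p = 0.185, 0.129, 0.292 and 0.225 with an estimated correlation. The call for butyrate over IL-13 ended without IL-13 replicate 1 (camera adjusted p = 0.0645, with 0.00309 to 0.292 over all alternatives). Fgf15, the hormone by which the ileum signals bile acid load to the liver, stood at 165 ± 9.11, 200.5 ± 6.43, 201 ± 19.9 and 439 ± 95 CPM untreated, with butyrate, with IL-13 and with both. It alone of the list was called in the interaction (0.85 ± 0.17, edgeR adjusted p = 0.018). That p was 0.062, 0.055, 0.059 and 0.062 without untreated replicate 2, butyrate replicate 1 and IL-13 replicates 1 and 2, with 3e-04 to 0.062 over all alternatives. Adjusted over the list alone 1 was higher and 2 lower, and camera gave adjusted p = 0.769.

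Ddit3 and Trib3, genes of the stress response, rose in all 4 comparisons of pairs. Ddit3, which encodes the transcription factor CHOP, stood at 53.8 ± 5.61 CPM untreated, 115 ± 14.2 CPM with butyrate, 171 ± 16.7 CPM with IL-13 and 278 ± 5.46 CPM with both. Trib3, one of its targets, stood at 70.4 ± 9.96, 173 ± 14.3, 264 ± 20.7 and 485 ± 83.6 CPM. In the unfolded protein response list, 8 of 20 genes rose with butyrate and 0 fell, 8 rose and 1 fell with butyrate over IL-13, and 10 rose and 3 fell with IL-13 over butyrate. These were 9 and 1, 8 and 1, and 10 and 3 adjusted over the list alone. Camera gave adjusted p = 0.00433, 0.00713 and 0.0263, and adjusted p = 0.264, 0.288 and 0.366 with an estimated correlation. With IL-13 over untreated 9 rose and 3 fell (9 and 3 adjusted over the list alone), but the list was not called (camera adjusted p = 0.0507). It was called there by fry (adjusted p = 0.000201), after thinning (0.0482) and without untreated replicate 1 (0.0437) or 2 (0.0254), butyrate replicate 1 (0.0488), IL-13 replicate 1 (0.0346) or 2 (0.0437) or butyrate + IL-13 replicate 3 (0.0469). Its adjusted p reached 0.408 with camera's estimated correlation. Of 16 p53 response genes IL-13 raised 9 and butyrate 4, and IL-13 over butyrate raised 8 and lowered 1. The counts adjusted over the list alone were the same. Camera gave adjusted p = 0.000995, 0.0118 and 0.0269, and adjusted p = 0.0802, 0.129 and 0.141 with an estimated correlation. The last call ended without butyrate replicate 3 (camera adjusted p = 0.0724). Butyrate over IL-13 raised 3 p53 response genes and lowered 1 (3 and 4 adjusted over the list alone; camera adjusted p = 0.589).

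Metabolic genes went both ways. Oxct1, which lets cells burn ketone bodies, rose from 356 ± 23.2 to 835 ± 55.8 CPM with IL-13 and to 476 ± 48.5 CPM with butyrate. The latter call (edgeR adjusted p = 0.00669) ended without untreated replicate 3 (0.052, with 0.00028 to 0.052 over all alternatives). In the list of fatty acid oxidation and ketogenesis, 8 of 23 genes rose and 7 fell with IL-13, and 3 rose and 3 fell with butyrate. With butyrate over IL-13 8 rose and 3 fell, and with IL-13 over butyrate 11 rose and 5 fell. Counts adjusted over the list alone were 8 and 7, 3 and 3, 9 and 3, and 11 and 5. Camera gave adjusted p = 0.672, 0.452, 0.00869 and 0.0624, and the called one had adjusted p = 0.366 with an estimated correlation. The last was called by fry (adjusted p = 0.00426) and by camera without butyrate + IL-13 replicate 2 (0.0423, with 0.00426 to 0.489 over all alternatives).

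In the cholesterol synthesis list IL-13 raised 1 and lowered 12 of 21 genes, and butyrate over IL-13 raised 8 and lowered 0. The counts were 1 and 13, and 12 and 0, adjusted over the list alone. Camera gave adjusted p = 0.00438 and 9.43e-05, and adjusted p = 0.482 and 0.357 with an estimated correlation. Butyrate over untreated lowered 1 gene of this list and IL-13 over butyrate raised 4 and lowered 6. They were 0, and 4 and 6, adjusted over the list alone, and camera gave adjusted p = 0.892 and 0.858. In the interaction edgeR called 0 genes of the fatty acid oxidation and cholesterol lists. At an unadjusted p under 0.05 these were 3 higher and 1 lower, and 7 higher, adjusted over the list alone 0 and 2 higher, and in DESeq2 1 and 0 higher. Both lists lay higher than additive (camera adjusted p = 0.00367 and 6.42e-08). Neither call held with an estimated correlation (camera adjusted p = 0.32 and 0.227) or with fry (adjusted p = 0.123 and 0.0594).

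Genes that sense or carry butyrate, with the histone deacetylases, were not called as a list by camera in any comparison. The adjusted p were 0.312 for IL-13, 0.258 for butyrate, 0.589 for butyrate over IL-13, 0.41 for IL-13 over butyrate and 0.86 for the interaction (camera). In that order edgeR called 3, 1, 2, 3 and 0 of 18 higher and 7, 1, 5, 6 and 0 lower. Those adjusted over the list alone were 3, 1, 3, 3 and 0 higher and 7, 1, 6, 6 and 0 lower. In the interaction 1 was higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 0. fry called the list lower with IL-13 (adjusted p = 0.00545), butyrate over IL-13 (0.0364) and IL-13 over butyrate (0.00313).

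In the antimicrobial and acute phase list, butyrate over IL-13 raised 7 of 15 genes and lowered 0. There were 9 and 0 adjusted over the list alone, and camera gave adjusted p = 0.00118 and adjusted p = 0.141 with an estimated correlation. IL-13 raised 5 and lowered 6 of them, butyrate raised 5 and lowered 3, and IL-13 over butyrate raised 6 and lowered 7. Adjusted over the list alone these were 5 and 6, 7 and 4, and 6 and 7, and camera gave adjusted p = 0.883, 0.308 and 0.48. fry called the list with IL-13 (adjusted p = 5.99e-05) and with IL-13 over butyrate (5.18e-06). In the interaction 3 were higher, among them Duoxa2 and Pigr, the carrier of IgA. There were 4 adjusted over the list alone, and camera gave adjusted p = 0.0104 and adjusted p = 0.199 with an estimated correlation. The call ended without IL-13 replicate 2 (camera adjusted p = 0.0791), butyrate + IL-13 replicate 3 (0.051) and both Lars2-high libraries (0.0768). Pigr lost its edgeR call without any of 9 libraries (adjusted p = 0.061 to 0.12), all but butyrate replicates 2 and 3 and butyrate + IL-13 replicate 1. Over all alternatives its adjusted p ran from 1.2e-06 to 0.12 (edgeR and DESeq2).

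In the list of regenerative and fetal-like epithelium, the growth factor gene Areg rose and Clu, a marker of revival stem cells, fell in all 4 comparisons of pairs (edgeR adjusted p from 8.44e-12 to 0.00554). Areg stood at 273 ± 2.98, 404 ± 14.9, 836 ± 45 and 1033 ± 38.6 CPM untreated, with butyrate, with IL-13 and with both, and Clu at 108 ± 5.96, 44.9 ± 3.21, 39.3 ± 5.38 and 15.2 ± 3.55 CPM. Of 14 genes, 4, 3, 2 and 2 rose and 3, 5, 3 and 4 fell with IL-13, butyrate, butyrate over IL-13 and IL-13 over butyrate. Adjusted over the list alone 4, 3, 2 and 2 were higher and 3, 5, 4 and 4 lower, and camera gave adjusted p = 0.539, 0.535, 0.161 and 0.86. fry called the list higher with IL-13 (adjusted p = 0.00179) and lower with butyrate over IL-13 (0.00332).

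Of 16 neuronal genes, which enteroendocrine cells also express in part, butyrate lowered 6 and raised 0, and over IL-13 lowered 8 and raised 2. These counts were 6 and 0, and 9 and 3, adjusted over the list alone. By camera the list had adjusted p = 0.0126 and 0.0356, and adjusted p = 0.129 and 0.154 with an estimated correlation. IL-13 raised 6 neuronal genes and lowered 1, and over butyrate raised 4 and lowered 4, with the same counts adjusted over the list alone. Camera gave adjusted p = 0.254 and 0.878 and fry adjusted p = 0.00191 and 0.223. In the interaction edgeR called 0 genes of the unfolded protein response, p53, regenerative and neuronal lists. At an unadjusted p under 0.05, 0, 0, 0 and 2 were higher and 2, 3, 3 and 5 lower. Adjusted over the list alone 0, 0, 0 and 1 were higher and 0, 0, 1 and 4 lower, and DESeq2 called 0, 0, 1 and 3. For the 4 lists camera gave adjusted p = 0.606, 0.127, 0.139 and 0.459. The p53 list was called there by fry (adjusted p = 0.0165) and by camera without butyrate replicate 3 (0.0306, with 0.0165 to 0.264 over all alternatives).

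The 6 libraries of a comparison of 2 groups can be split into groups of 3 in 10 ways, which are too few for a share under 0.05. The real splits, each the 1 of 10 with the most genes, called 5977 (IL-13), 1086 (butyrate), 2912 (butyrate over IL-13) and 6564 genes (IL-13 over butyrate) in edgeR. The highest of the other splits called 0, with 107 to 2229 at an unadjusted p under 0.05. For the interaction, 2 of 100 splits of the 12 libraries, the real one included, called at least its 119 genes. In every other split the libraries of a group lay further apart (biological coefficient of variation of 16.1% to 31.9%, against 10.2%), and 98 of the 99 mixed libraries with and without IL-13 in a group. These splits therefore do not decide whether chance could give the real count. The highest other split called 2851 genes, several times the real count, and what sets it apart is not known. That split had 5 of the libraries given IL-13 on one side of the contrast, so that the IL-13 effect enters it. So had 5 others in which edgeR called 0 (2230 to 4238 at an unadjusted p under 0.05).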
